A study of Homo sapiens with 61 samples.

How the data were processed

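Gene expression was measured on 61 Affymetrix arrays of 54675 probe sets. Each array carried RNA from human tissue dissected by laser under the microscope, from areas that the labels describe as enriched for the endothelium of tumor vessels. Per the labels' protocols, RNA was isolated from the captured tissue, amplified linearly by repeated in vitro transcription and labelled with biotin. Such amplification shortens the product towards the 3' end of each transcript, so probe sets far from it lose signal.

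The deposited values are log2 values. MAS5 made them, per the submitters' processing notes, and the version, the scaling between arrays and the treatment of low signals are not given in the sources used here. The lowest value was the log2 of 10, 3.32, on 57 arrays and lay between 2.88 and 3.26 on the other 4, which were 1 normal liver, 1 HCC primary without metastasis and 2 HCC primaries with metastasis. These 4 arrays held 15.5% to 22.6% of probe sets at their floor, against 24.0% to 42.4% on the 57, and their 95th percentiles were 8.64 to 9.17 against 9.24 to 9.68. Array medians ran from 3.85 to 5.24, and these 4 arrays had the highest, from 5.12 to 5.24. They thus differed from the 57 in more than their floor. A value at the floor gives only an upper limit, so a fold against a group that lies wholly at its floor is written as "at least". Where only arrays of the lower group lie at the floor, the difference is a lower limit too, and its SE leaves out the spread below the floor. With arrays of the higher group at the floor as well, a difference is no limit in either direction. The number of arrays limits the precision.

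The platform annotation gave 1 gene symbol for 41097 probe sets, several for 1801 and none for 11777. Symbols were updated through the gene identifier for 41043 probe sets. Probe sets with several symbols were left out, and each gene was represented by its brightest probe set over all arrays, which left 19740 genes. Genes of the Y chromosome, XIST and TSIX were left out. A gene was tested if its value reached the median of all probe sets on at least 5 arrays, which 16880 genes did.

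Groups came from the labels. Primary tumor and metastasis of one patient share a code, and this pairing gave 7 colon pairs and 10 liver tumor pairs. Deviations from the group means correlated within every pair, the lowest at 0.21 for colon and 0.22 for liver tumors, and all 7 and all 10 metastases correlated best with their own primary. A check for exchanged samples used transcripts that differ between the sexes. The brightest probe sets gave an opposite sign in 2 of the 17 pairs and the mean of the probe sets in 3. With a margin of 3 log2 units required on both arrays, 9 pairs matched, 0 were opposite and 8 gave no clear answer. The margin was set after these values were seen, so the check leaves an exchange possible.

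Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend and robust estimation), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All tests were two-sided. Paired comparisons kept the patient as a block. The 2 comparisons of HCC primaries shared one fit with normal liver, in which the HCC effect was the mean of the 2 HCC groups, and the comparison of lung metastases left out the primaries of patients with a lung metastasis array, so that each patient gave 1 array. No batch is named in the sources used here, so none could be tested.

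The 26 gene lists for cell types and pathways, the comparisons, the named genes and most alternatives were fixed before the data were examined. Lists were tested with camera at an inter-gene correlation of 0.01 and again with an estimated correlation. A list score, the mean log2 value of the measured members on each array, was added after seeing the data, with exact sign flips of the pairs, exact permutation, or 100000 permutations where exact enumeration was too long. Named genes are the 10 largest rises and 10 largest falls among genes past the threshold and the 4 members of smallest p of each list past it under camera; where no gene passed, they are the 3 of smallest p in each direction. ALB, PECAM1, CLEC14A, CDH5 and KRT19 were named after their values were seen. RNA quality was the mean 3'-to-5' log2 difference of the ACTB and GAPDH control probe sets.

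Alternatives were quantile normalization, other filters, the mean of all probe sets, array weights, the 3'-to-5' difference as a covariate, fits without the patient block, other sample sets and leaving out each pair or each array of the small groups. A common floor, the omission of the 4 arrays, a linear regression of the list score, camera with the 3'-to-5' covariate and camera leaving out each pair or array of the small groups were added after seeing the data. The planned floors for linear values were not run, because the values are log2. On simulated data with 200 changed genes among 16880, a change of 2 log2 units was recovered for 48.5% of genes in the colon pairs, 82.0% in the liver tumor pairs, 51.0% for their difference, 44.5% in the comparison of HCC primaries, 59.0% against normal liver, 87.0% in the comparison of lung metastases with primaries, 43.0% in that of lung with adrenal metastases, and 0.500% in that of CC with HCC, where a change of 4 was recovered for 75.0%. The simulated noise was normal and independent between genes, unlike genes that vary together, so these rates may not hold for the real data. At a change of 2 the false share of calls reached 10.4% for lung against adrenal metastases and 9.23% against normal liver. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.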

Results

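The series holds colon primaries (n = 7) and their liver metastases (n = 7), normal liver from patients with hemangioma (n = 5), primaries of hepatocellular carcinoma (HCC) without (n = 10) and with metastasis (n = 5), HCC metastases to the adrenal gland (n = 3) and lung (n = 12), and primaries (n = 4) and lymph node metastases (n = 3) of cholangiocarcinoma (CC), a tumor of the bile duct. One array each came from a gastric primary and from the primary and lymph node metastasis of a mixed HCC and CC tumor and of an angiosarcoma. Values are log2 signals, given as mean ± SD or as log2 fold change ± SE. p-values are from limma with Benjamini-Hochberg adjustment unless another test is named.

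Although the captured areas were labelled as enriched for endothelium, epithelial transcripts differed widely between tumor types. The hepatocyte list, genes of plasma proteins made by the liver, had a level of 13.10 ± 0.30 (SD, n = 5) in normal liver, 12.08 ± 0.45 (SD, n = 10) in HCC primaries without metastasis and 5.97 ± 2.62 (SD, n = 7) in colon primaries. The colon epithelium list had a level of 9.26 ± 0.69 (SD, n = 7) in colon primaries and 4.96 ± 0.32 (SD, n = 5) in normal liver. The pan-endothelial list lay at 5.76 ± 0.59 (SD, n = 5) in normal liver and 4.33 ± 0.23 (SD, n = 7) in colon primaries. HCC and normal liver are compared below; the colon levels were not tested against the others.

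**Figure D1:**
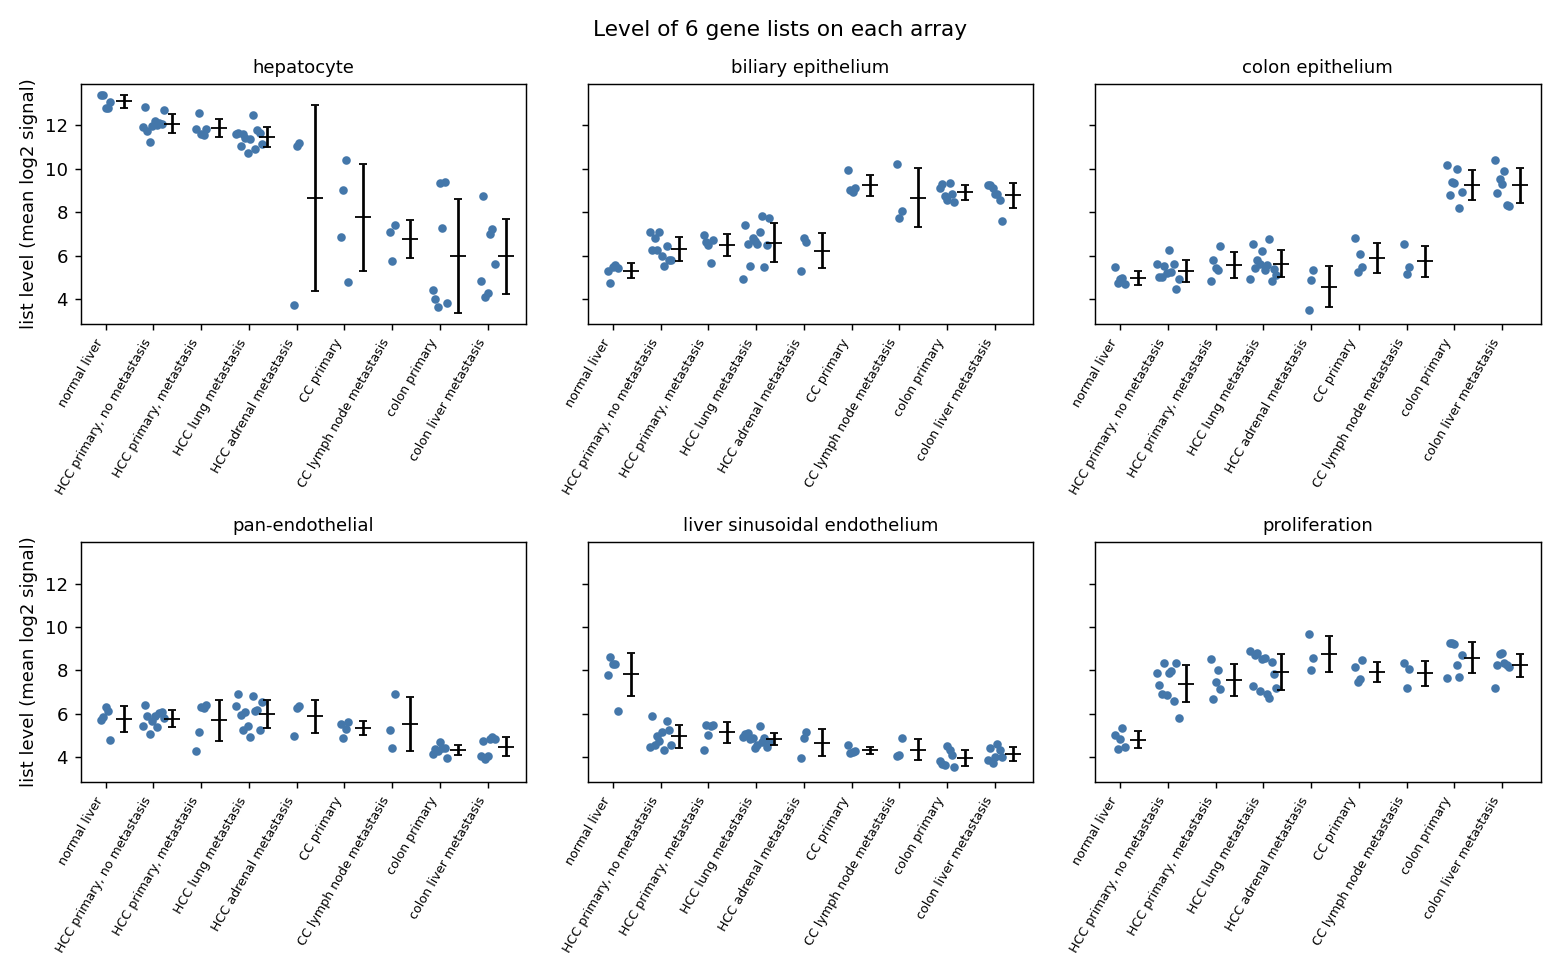
Mean log2 signal of 6 gene lists (y axis) on each array (points), by group (x axis), with mean and SD (black bars). The hepatocyte list was near 13.10 in normal liver and spread widely in colon arrays, and the colon epithelium list was near 9.26 in colon primaries.

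HCC primaries were set against normal liver to ask what differs in tumor tissue. CCL20, a chemokine that attracts lymphocytes and dendritic cells, rose by 6.15 ± 0.68 (SE), and SPINK1, a trypsin inhibitor, by 5.21 ± 0.98. CXCL14, another chemokine, fell by 6.17 ± 0.33, CYP1A2, a drug-metabolizing enzyme, fell by 6.17 ± 0.63, and FOS, an immediate early transcription factor, fell by 5.86 ± 0.58. The other large rises were SULT1C2, RRM2, TMEM45B, DTNA, HKDC1, IGSF3, IQGAP3 and TOP2A, and the other large falls were LINC01093, LINC01554, CNDP1, SLCO1B3, ADRA1A, NAT2 and HPD. In all, 1007 of 16880 genes passed the threshold, 435 higher and 572 lower in 15 HCC primaries than in 5 normal livers.

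Of the proliferation list, 18 of 20 members rose, among them RRM2 by 4.72 ± 0.56 (SE), TOP2A by 4.10 ± 0.44 and CENPF by 3.14 ± 0.41, and KIF20A, at its floor in all 5 normal livers, was at least 14.2-fold higher. All 7 measured metallothioneins, metal-binding proteins, fell, MT1F by 5.25 ± 0.63 and MT1M by 5.09 ± 0.65. Of the drug and bile acid metabolism list, 12 of 18 fell, CYP2B6 by 3.80 ± 0.70 and CYP4A11 by 3.52 ± 0.49. Of the liver sinusoidal endothelium list, 12 of 16 fell, FCN2 by 4.65 ± 0.54, CLEC1B by 4.47 ± 0.52, CLEC4G by 3.86 ± 0.49 and CLEC4M by 3.83 ± 0.52, whereas 1 of 19 pan-endothelial genes fell and 0 rose, and that list's mean difference was -0.03. CLEC4G was at its floor on 11 of the 15 HCC arrays, FCN2 on 8, CXCL14 on 13 and MARCO on 13, so their falls are lower limits. The oncofetal and progenitor list had 4 of 11 members higher, CD24 by 3.57 ± 0.60, GPC3 by 3.61 ± 1.04 and IGF2BP3 by 2.71 ± 0.64. In the immediate early list 4 of 13 members fell and 1 rose; FOSB fell by 5.11 ± 0.54 and EGR1 by 2.64 ± 0.51.

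With the estimated correlation these 6 lists kept adjusted p-values of 0.0121 for proliferation, 0.0121 for metallothioneins, 0.00364 for drug metabolism, 0.00509 for sinusoidal endothelium, 0.0363 for the oncofetal list and 0.0127 for immediate early genes. Of the hepatocyte list 4 of 20 members fell, among them HAMP by 3.40 ± 0.69 and TTR by 2.54 ± 0.54 (adjusted p = 0.0638 with an estimated correlation). Of the biliary list 1 member, SOX9, rose by 2.56 ± 0.62 (adjusted p = 0.0637 with an estimated correlation), and of the macrophage list 1, MARCO, fell by 2.94 ± 0.30 (adjusted p = 0.613 with an estimated correlation). Without normal liver array 2 the biliary and macrophage lists did not pass by camera (adjusted p = 0.0840 and 0.0812), nor without array 5 with metastasis (0.0514 and 0.0800), nor did the macrophage list without normal liver array 1 (0.0946) or without the 4 arrays of another floor (0.117). Adjusted over the list alone, 19 proliferation genes were higher and 14 sinusoidal and 16 drug metabolism genes lower. Without normal liver array 5 the count was 624, and without the 4 arrays of another floor it was 1013, of which 733 were shared.

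**Figure D2:**
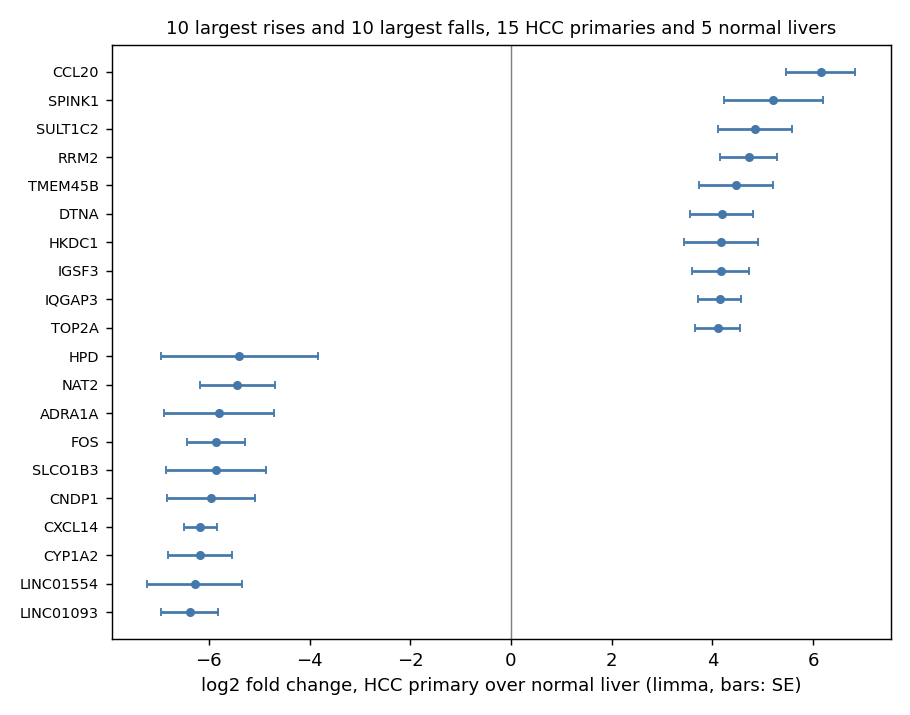
Log2 fold change of HCC primaries over normal liver (x axis) for the 10 largest rises and 10 largest falls among genes past the threshold (y axis), with bars for SE. CCL20 stands at 6.15 and LINC01093 at -6.38.

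CC primaries were set against HCC primaries with metastasis to compare tumor types of the liver. CFTR, the chloride channel of bile duct cells, rose by 6.20 ± 0.72 (SE), the epithelial splicing factor ESRP1 by 5.11 ± 0.62 and the transcription factor SOX4 by 4.49 ± 0.42; CFTR was at its floor on 3 of the 5 HCC arrays. APOA1, the main protein of high-density lipoprotein, fell by 7.15 ± 0.80, antithrombin, SERPINC1, fell by 6.53 ± 0.98, and coagulation factor F12 fell by 5.68 ± 0.51. Other large rises were SYT13, PFKP, S100A6, PROM1, CDH6, BICC1 and RAB25, and other large falls KNG1, F2, AHSG, F9, ADH1B, A1BG and AGXT. In all, 193 genes passed, 71 higher and 122 lower in 4 CC than in 5 HCC primaries.

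Of 12 biliary genes 2 rose over all genes tested and 8 adjusted over the list alone, and the list kept adjusted p = 0.00861 with an estimated correlation. Of 20 hepatocyte genes 4 fell, and 15 adjusted over the list alone (adjusted p = 0.221 with an estimated correlation). Of 18 drug metabolism genes 5 fell, SULT2A1 by 5.10 ± 0.76 and BAAT by 3.36 ± 0.58 (adjusted p = 0.124 with an estimated correlation). Of 16 sinusoidal genes 1, DNASE1L3, fell by 3.15 ± 0.61 (adjusted p = 0.357 with an estimated correlation). None of 18 fibroblast and collagen genes passed over all genes, and 11 were higher adjusted over the list alone, with POSTN at 4.08 ± 0.95 and VCAN at 3.46 ± 0.92 (adjusted p = 0.357 with an estimated correlation). By the preset correlation alone, hypoxia and glycolysis (0.53), interferon response (0.70), immediate early (0.77) and oxidative phosphorylation genes (0.38) passed as well (adjusted p of at least 0.367 with an estimated correlation). Without CC array 1 hypoxia and glycolysis was 0.27 (adjusted p = 0.229 by camera), without CC array 4 oxidative phosphorylation was 0.18 (0.341), and without CC array 2 immediate early was 0.48. Oxidative phosphorylation also missed the threshold by camera without HCC array 2 or 3 (0.105 and 0.111), and hypoxia and glycolysis without HCC array 3 or 5 (0.115 and 0.104). Without the 4 arrays of another floor, 2 of them among the 5 HCC arrays, the count was 41. Then 1 biliary, 1 hepatocyte, 0 drug metabolism and 0 sinusoidal genes passed the threshold. These lists still passed by camera, oxidative phosphorylation did not (adjusted p = 0.0762), and hypoxia and glycolysis was larger, at 0.83 (0.00215). The count was 86 without CC array 2 and 81 without HCC array 4.

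HCC primaries with and without metastasis were compared to ask what separates tumors that spread. DYNC1I1, a subunit of the motor protein dynein, rose by 2.69 ± 0.42 (SE), and NPFFR2, a neuropeptide receptor at its floor in all 10 primaries without metastasis, was at least 5.29-fold higher if the 1 of 5 arrays with metastasis that also lay at its floor is counted at that floor. CCDC88C, a regulator of Wnt signalling, fell by 2.91 ± 0.49. These 3 genes were all that passed in 5 against 10 arrays, and 1631 had an unadjusted p under 0.05. Interferon response genes differed by a mean of -0.65, with XAF1 at -1.99 ± 0.69 and 0 of 17 past the threshold (adjusted p = 0.693 with an estimated correlation), and drug metabolism genes by -0.86, with 0 of 18 past it (adjusted p = 0.693 with an estimated correlation) and -0.52 without array 1 with metastasis. The median over all genes was 0.11. Without the 4 arrays of another floor, 2 of them among the 5 arrays with metastasis, 0 genes passed. With the mean of all probe sets 11 did.

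HCC lung metastases were set against 13 HCC primaries of other patients, 10 of them from patients without metastasis. VWF, the von Willebrand factor of endothelial cells, rose by 2.54 ± 0.43 (SE), and TSC22D3, a gene induced by glucocorticoids, was 3.99-fold higher. These were the 2 genes past the threshold in 12 against 13 arrays, and 2738 had an unadjusted p under 0.05. Of 14 hypoxia and glycolysis genes 0 passed over all genes and 9 were higher adjusted over the list alone, with EGLN3 at 2.01 ± 0.53 and PGK1 at 1.40 ± 0.38 (adjusted p = 0.172 with an estimated correlation). Its list score was higher by 0.90 (permutation adjusted p = 0.0065). With the 3'-to-5' difference as a covariate the score was higher by 0.74 (adjusted p = 0.0733 by regression). In the 2 patients with both arrays the score differed by -0.60 and 0.21, metastasis minus primary. Of 20 hepatocyte genes 8 were lower adjusted over the list alone, the 2 of smallest p being APOH and TF (adjusted p = 0.172 with an estimated correlation), and the list score differed by -0.61 (permutation adjusted p = 0.0419), and by -0.51 without the 4 arrays of another floor (adjusted p = 0.142 by regression). SFTPC, the surfactant protein of lung alveoli, differed by 2.37 ± 0.74, and 4 of 10 lung epithelium genes were higher adjusted over the list alone (adjusted p = 0.800 with an estimated correlation). By camera's preset correlation alone, 6 further lists passed, with mean differences of 0.84 for fibroblast and collagen matrix, 0.48 for proliferation, 0.40 for oxidative phosphorylation, -0.46 for T cells, 0.82 for metallothioneins and 0.34 for pan-endothelial genes (adjusted p = 0.800 with an estimated correlation for each). Without the 4 arrays of another floor proliferation was 0.26, oxidative phosphorylation 0.23 (adjusted p = 0.0634 by camera) and metallothioneins 0.67 (0.0552). With the 3'-to-5' difference as a covariate metallothioneins were 0.64 (adjusted p = 0.153 by camera) and pan-endothelial genes 0.36 (0.0548), and ribosomal proteins, not past the threshold without it, were -0.32 (0.0066). The 3'-to-5' difference was 3.87 ± 0.82 (SD, n = 12) in metastases and 5.07 ± 1.48 (SD, n = 13) in primaries (permutation p = 0.0208, adjusted over 7 comparisons 0.146). With that difference as a covariate 0 genes passed, and with all primaries and the patient as a random block 0 did.

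Lung and adrenal metastases of HCC were compared to ask how the site matters. No gene passed in limma's test of 12 against 3 arrays, and 1700 had an unadjusted p under 0.05. TMEM178B, of smallest p, differed by -3.44 ± 0.56 (SE; adjusted p = 0.127), and PIGR, the receptor that carries immunoglobulins across epithelia, by 4.83 ± 0.91 (adjusted p = 0.186). Hepatocyte genes differed by a mean of 2.79, and 14 of 20 were higher in lung metastases adjusted over the list alone (adjusted p = 0.480 with an estimated correlation). By the preset correlation alone, drug metabolism (2.43), colon epithelium (1.06), lung epithelium (1.66), proliferation (-0.85), interferon response (0.90), metallothioneins (1.09) and ribosomal proteins (-0.35) passed as well (adjusted p of at least 0.480 with an estimated correlation). Most of these differences were smaller without adrenal metastasis array 1, whose hepatocyte level was 3.72 against 11.07 and 11.20 on the other 2 and whose adrenal gland list level was 5.54 against 3.48 and 3.58. The means were then 0.32 for hepatocyte (adjusted p = 0.649 by camera), 1.21 for drug metabolism, 0.52 for colon epithelium, -0.39 for proliferation (0.127), 0.11 for interferon response (0.649), 0.98 for metallothioneins (0.0551) and -0.20 for ribosomal proteins (0.191). Without array 2 metallothioneins were 0.69 (0.295) and ribosomal proteins -0.34 (0.102). Without adrenal metastasis array 1, 2 or 3 the count was 1, 10 or 99.

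Metastases outside the liver were set against the primary liver tumor of the same patient. No gene passed limma's test in 10 pairs, and 1857 had an unadjusted p under 0.05. HMGB2, a chromatin protein, was higher in the metastasis in 10 of 10 pairs, by 0.97 ± 0.17 (SE; adjusted p = 0.344), and GPD1, an enzyme of glycerol metabolism, was lower in 10 of 10, by -1.44 ± 0.23 (adjusted p = 0.284). Of 20 proliferation genes 11 were higher adjusted over the list alone, with BUB1B at 1.07 ± 0.24 and BIRC5 at 1.01 ± 0.26 (adjusted p = 0.529 with an estimated correlation). The list score was higher in 9 of 10 pairs, by 0.58 (exact sign-flip p = 0.00977, adjusted 0.127). Without the 4 arrays of another floor the mean difference of proliferation genes was 0.45. Hepatocyte genes differed by a mean of -1.66 (adjusted p = 0.627 with an estimated correlation), with the first adrenal pair at -8.11 and a mean of -0.94 without it; in that pair the adrenal gland list was higher in the metastasis by 1.75. By the preset correlation alone, drug metabolism (-0.60), pan-endothelial (0.27), fibroblast and collagen matrix (0.54), neutrophil (-0.49), interferon response (0.33), immediate early (0.31) and oxidative phosphorylation genes (0.24) passed as well (adjusted p of at least 0.627 with an estimated correlation). Each lost the threshold under some omission. Leaving out the 4 arrays of another floor also takes out the second adrenal and first HCC lung pairs. Pan-endothelial was then 0.18 (adjusted p = 0.0921 by camera), neutrophil -0.16 (0.362), interferon response 0.06 (0.362) and oxidative phosphorylation 0.07 (0.307). Without the first adrenal pair drug metabolism was -0.36 (0.0730), without the angiosarcoma pair immediate early was 0.21 (0.200), and without the third adrenal pair 0.27 (0.0513). Without the third CC pair pan-endothelial was 0.12 (0.205), fibroblast and collagen matrix 0.37 (0.0596), interferon response 0.17 (0.205) and immediate early 0.24 (0.150). Without the first CC pair fibroblast and collagen matrix was 0.84 and neutrophil -0.39 (0.0700), and without the second adrenal pair neutrophil was -0.36 (0.0833), pan-endothelial 0.17 (0.0465) and oxidative phosphorylation 0.15 (0.0181). Without the first HCC lung pair interferon response was 0.13 (0.254) and neutrophil -0.33 (0.0943), and without the second fibroblast and collagen matrix was 0.36 (0.0362).

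Colon cancer metastases in the liver were set against the colon primary of the same patient. No gene passed limma's test in 7 pairs. An unadjusted p under 0.05 was found for 711, fewer than the share of 0.05 that chance gives on average among 16880 genes. SFRP2, a secreted modulator of Wnt signalling, was lower in 7 of 7 pairs, by -2.37 ± 0.34 (SE; adjusted p = 0.210; at its floor on 6 of 7 metastases), and ITGA5, an integrin that binds fibronectin, was higher in 7 of 7, by 1.41 ± 0.30 (adjusted p = 0.912). Macrophage genes differed by a mean of 0.59, with C1QA at 1.07 ± 0.40 and 0 of 13 past the threshold (adjusted p = 0.529 with an estimated correlation). The score was higher in 6 of 7 pairs (exact sign-flip p = 0.0312, adjusted 0.271). Interferon response genes differed by -0.43 and proliferation genes by -0.33 (adjusted p = 0.635 with an estimated correlation for both), and mesenchymal transition genes by 0.35 (adjusted p = 0.529 with an estimated correlation). Without pair 3 interferon response was -0.24 (adjusted p = 0.178 by camera), without pair 2 proliferation was -0.22 (0.0663), and without pair 2, 5 or 6 mesenchymal transition was 0.32, 0.31 or 0.30 (0.0527, 0.0899 and 0.133).

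The difference between the metastasis effects of colon and liver tumor pairs was tested as an interaction. The colon metastases lay in the liver and the others in lymph node, adrenal gland or lung, so tumor type cannot be told apart from site. The liver tumor pairs also pool HCC, CC, mixed and angiosarcoma pairs. No gene passed limma's test over 17 pairs, and 1456 had an unadjusted p under 0.05. CKS2, a cell cycle protein, had a difference of -1.53 ± 0.31 (SE; adjusted p = 0.410) and NTN4, a basement membrane protein, one of 2.52 ± 0.59 (adjusted p = 0.474). Of 20 proliferation genes 9 were lower adjusted over the list alone, with PRC1 at -1.54 ± 0.35 (adjusted p = 0.184 with an estimated correlation). The list score differed by -0.91 between colon and liver tumor pairs (exact permutation p = 0.00406, adjusted 0.106).

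**Figure D3:**
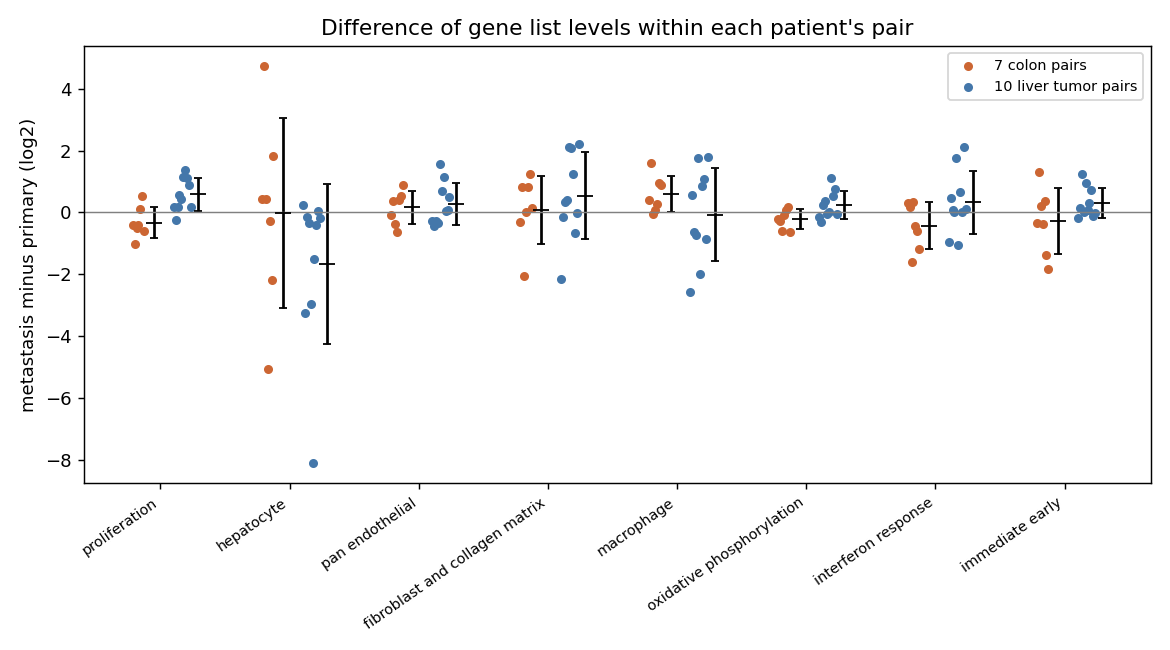
Difference of 8 gene list levels between metastasis and primary (y axis, log2) within each patient's pair (points) for 7 colon and 10 liver tumor pairs, with mean and SD (black bars). Proliferation was higher in the metastasis in 9 of 10 liver tumor pairs and in 2 of 7 colon pairs.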

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

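The correlations over hepatocyte genes and over the lung metastases were set out before their results were seen; all other tests of explanations here were chosen after, as were the rules for a level under 6 and for the gastric array.

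In 2 colon primaries hepatocyte genes stood at 9.33 and 9.39, against 3.64 to 7.27 in the other 5, and over 38 hepatocyte genes these arrays followed normal liver with a Spearman rho of at least 0.83, across genes, which are not independent replicates. ALB reached 10.59 and 11.46 on them, against 12.98 to 14.49 in normal liver. Hepatocyte cells or RNA in the captured material may account for this. An exchange of primary and metastasis within a pair cannot be told apart from it, because 3 of the 5 metastases of the other patients also lay under 6. The metastases of the same 2 patients stood at 4.26 and 7.21. In the second pair the metastasis had a rho of 0.51 and ALB at 7.84. An exchange there would still leave a colon primary at 7.21, within the range of the other 5, so it would not remove all hepatocyte signal. Expression of liver genes by the tumor itself was not tested. Hepatocyte signal was not limited to those 2 colon primaries. The gastric primary, which has no metastasis array here, stood at 8.53, with a rho of 0.667 and ALB at 10.35. Colon primary 5, the next highest of the colon primaries, had a rho of 0.46 and ALB at 9.15.

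The sinusoidal endothelium list was lower in HCC than in normal liver by 2.81. The tables argue against 3 technical explanations, the first only under an assumption. A lower share of endothelial cells would lower the pan-endothelial list alike if each cell kept its levels of these genes. That list differed by -0.0135 ± 0.306 (SE), and its 10 members bright enough to show such a fall by -0.34 ± 0.36. Those members did not move together, and more were lower than higher. TEK (5.24 in HCC, 7.28 in normal liver), KDR (6.56 and 7.48) and ERG (5.53 and 6.49) were lower. ROBO4, MMRN2, FLT1 and CDH5 were lower by less. PECAM1 was higher (8.75 and 7.54), and CLDN5 (6.74 and 6.52) and EMCN (6.60 and 6.34) were slightly higher. A lower share offset by higher levels per cell stays open. With the 3'-to-5' covariate the sinusoidal difference was -2.89 ± 0.31, and without the 4 arrays of another floor -2.85 ± 0.41. A loss of sinusoidal character in tumor vessels is a hypothesis only, drawn from the same data, and was not itself tested. A different mix of vessel types in the captured areas stays open.

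The hypoxia and glycolysis list was higher in HCC lung metastases than in primaries of other patients by 0.90 ± 0.22 (SE). Of those 13 primaries, 10 came from patients without metastasis, so site cannot be told apart from patient and spread. A response of the tumor to its site stays untested. In the 2 patients with both arrays the list differed by -0.60 and 0.21, metastasis minus primary. Over all 12 lung metastases it did not rise with the lung epithelium list (Pearson r = -0.351, permutation p = 0.266, 95% interval -0.77 to 0.28; Spearman rho = -0.357, permutation p = 0.256; 1 relation computed), which argues against lung tissue as its source. That argument rests on the 2 arrays farthest from the median, since without them r was 0.0289 with an interval of -0.612 to 0.647, too wide to exclude lung tissue. RNA quality cannot be told apart, since with the 3'-to-5' covariate the difference was 0.74 ± 0.24, with adjusted p = 0.00031 by camera and 0.0733 by regression of the list score. Without the 4 arrays of another floor it was 0.82 ± 0.21 and the list stayed past the threshold (adjusted p = 6.05e-06 by camera, 0.0207 by regression), which argues against these arrays as the whole cause, by a bound widened after these values were seen; by the first bound, most of the difference kept by more than 2 SE, they stayed open.

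No other split reached the real count for HCC against normal liver or for CC against HCC, which argues against chance as far as 100 splits can. For HCC against normal liver 1 of 100 splits, the real one, gave as many as 1007 genes, and the highest other gave 8; for CC against HCC it was 1 of 100, with 193 genes and a highest other of 32. For lung metastases against primaries 2 of 100 splits gave 2 genes or more, but the highest other equals the real count of 2, so the count is not taken to exclude chance. For HCC primaries with against without metastasis 8 of 100 splits gave 3 genes or more and the highest other gave 66, so chance could not be excluded. What lay behind the split with 66 genes was not tested. A real count of 0 is met by every split, so the splits say nothing about chance for lung against adrenal metastases (100 of 100, highest other 54), colon pairs (64 of 64, highest other 0), liver tumor pairs (100 of 100, highest other 0) or their difference (100 of 100, highest other 0).

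Single arrays stood far from their group in 17 of 180 checks. Chance flags about 1 in 20 groups, here 9 if the checks were independent, but scores of the same array are related. Several flags lay on arrays of another floor. In normal liver these were oxidative phosphorylation and the 95th percentile. Among HCC primaries they were hypoxia, oxidative phosphorylation and the 95th percentile without metastasis, and hepatocyte with metastasis. Among colon liver metastases one array each stood at 7.59 for biliary epithelium (others 8.59 to 9.27), 5.73 for red blood cells (4.03 to 4.52) and 7.21 for proliferation (8.14 to 8.81). Among normal livers the values were 9.42 for oxidative phosphorylation (10.78 to 11.21), 8.64 for the 95th percentile (9.30 to 9.54) and 6.85 for the 3'-to-5' difference (4.68 to 5.30). Among HCC primaries without metastasis they were 9.11 for fibroblast and collagen matrix, 5.78 for B cells and lymph node, 7.39 for hypoxia, 9.09 for oxidative phosphorylation and 8.69 for the 95th percentile. Among CC primaries they were 9.95 for biliary epithelium, 5.57 for B cells and 11.69 for oxidative phosphorylation, and among HCC primaries with metastasis 12.57 for hepatocyte, 3.98 for B cells and 5.23 for macrophage genes.

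The metastasis effect differed between colon and liver tumor pairs under camera's preset correlation for 6 lists, hepatocyte (1.65), macrophage (0.66), proliferation (-0.91), interferon response (-0.76), immediate early (-0.60) and oxidative phosphorylation (-0.46), and for 0 of them with an estimated correlation or with the list score. Without the 4 arrays of another floor oxidative phosphorylation was -0.28 (adjusted p = 0.0769 by camera) and interferon response -0.49. Single pairs moved 3 of these lists. Hepatocyte was 0.86 without colon pair 2 (adjusted p = 0.0843 by camera), 2.49 without colon pair 4 and 0.93 without the first adrenal pair (0.0338). Macrophage missed the threshold without colon pair 2 (0.49), 6 (0.60) or 7 (0.62), the first CC pair (0.39), the angiosarcoma pair (0.60), the mixed tumor pair (0.59) or the first adrenal pair (0.45), and immediate early without colon pair 6 (-0.42) or 7 (-0.34) or the angiosarcoma pair (-0.50). The gastric primary, in no comparison, exceeded every normal liver by over 1 log2 unit for biliary epithelium (8.85), colon epithelium (8.24), fibroblast and collagen matrix (9.45), proliferation (9.10), Wnt targets (7.17) and the oncofetal list (7.98).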

How the results depend on the processing

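The common floor, the omission of the 4 arrays of another floor, the list score and its regression and leaving out arrays or pairs for lists were chosen after seeing the data. Leaving out the 4 arrays also means fewer samples. It removes 2 of the 5 HCC primaries with metastasis, and with them the second adrenal and first HCC lung pairs. Where a gene or list loses the threshold under this omission, an effect of the 4 arrays cannot be told apart from lower power. Lower power alone would not move a mean difference or raise a count. For HCC against normal liver 1013 genes passed without the 4 arrays, and 733 of them were among the 1007 of the main fit. Whether the processing of the 4 arrays or their patients moved such values was not tested. The paired counts of 0 genes, for colon pairs, liver tumor pairs and their difference, stayed 0 under every alternative run, the fit with no replicate block included, and the cause of each shift below was not tested. For HCC primaries with against without metastasis the 3 genes became 11 with the mean of all probe sets, 1 with array weights, 1 with only the HCC primaries in the fit (fewer samples), 0 without the 4 arrays, and 3 to 26 leaving out each of the 5 arrays with metastasis (5 without array 1 or 3, 26 without array 5). For HCC against normal liver the 1007 became 2654 with array weights and 624 to 1098 leaving out each normal liver or HCC primary with metastasis. For lung metastases against primaries the 2 became 1 with quantile normalization, 23 with the stricter filter, 18 with array weights, 0 with the 3'-to-5' covariate, 0 with the random block and 4 without the 4 arrays. For lung against adrenal metastases the 0 became 1 with array weights and 1 to 99 leaving out each of the 3 adrenal arrays. For CC against HCC the 193 became 96 with no filter, 121 with the mean of all probe sets, 755 with all HCC primaries (more samples), 41 without the 4 arrays and 81 to 297 leaving out each array (CC arrays 1 to 4 gave 93, 86, 297 and 123, HCC arrays 3 and 4 gave 111 and 81).

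The lists past the threshold fell to 0 with the estimated correlation in the colon pairs (from 4), liver tumor pairs (9), their difference (6), HCC primaries with against without metastasis (2), lung metastases against primaries (9) and against adrenal metastases (8), and to 1 from 9 for CC against HCC. The list score gave 0 in these comparisons, except 2 for lung metastases against primaries. For the colon pairs and for CC against HCC the number of arrays nearly fixes that 0: the smallest p possible is 0.0156 and 0.00794, and 9 and 5 of the 26 lists would have to reach it, so it says nothing about stability. Of single named genes, 4551 values kept their direction and side, 141 lost and 36 gained the threshold and 6 turned: with CC pairs only, SPARC (-0.0561), CXCR2 (0.21), ATP5F1A (-0.0320), ATP5F1B (-0.53) and COX5A (-0.0164) in the liver tumor pairs, and with the mean of all probe sets FLT1 (0.39) in lung metastases. None of the 6 had passed the threshold. A value counts as kept also where the gene passed under neither setting, as for most values in the comparisons with 0 genes. Of the 4551, 2108 came from leaving out 1 pair or array, and such fits share most of their arrays. The count is therefore no measure of how stable the genes past the threshold were. Of list values, 97 kept their side and 115 lost it. The planned floors for linear values were not run, since the values are log2. Genes at the floor limit what signal over background can show, with up to 42.4% of probe sets there.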

Other observations

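The test of the list score in this part was chosen after the data were seen, and the camera tests were planned. The proliferation list was higher in the metastasis in 5 of 5 HCC pairs, by a mean of 0.94 ± 0.46 (SD), with 1.12 to 1.37 in the 3 adrenal pairs and 0.18 to 0.88 in the 2 lung pairs, against -0.26 to 0.45 in the 3 CC pairs. In 2 of these HCC pairs, second adrenal (1.37) and first lung (0.88), the primary was among the 4 arrays of another floor. The pan-endothelial list was also higher in 5 of 5 HCC pairs, by 0.49 ± 0.46, with 2 pairs near 0 (0.03 and 0.09), and over its 10 brighter members 1 of the 5 pairs was lower (-0.13). For it the second adrenal and first lung pairs gave 1.145 and 0.09. With 5 pairs the smallest two-sided p of exact sign flips exceeds 0.05, so no test was run. One of the 2 HCC lung pairs had the lung epithelium list higher by 5.24, and the first adrenal pair, whose metastasis had a hepatocyte level of 3.72, had the adrenal gland list higher by 1.75.

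In HCC against normal liver the remaining lists did not pass under camera. Mean differences were 0.43 for tumor endothelium, 0.13 for pericytes and smooth muscle, -0.36 for fibroblast and collagen matrix, 0.23 for B cells and lymph node, -0.11 for T cells, -0.33 for neutrophils, -0.40 for red blood cells, 0.06 for lung epithelium, -0.30 for the adrenal gland, 0.47 for colon epithelium, -0.06 for hypoxia and glycolysis, -0.19 for interferon response, -0.01 for mesenchymal transition, 0.12 for Wnt targets, 0.12 for ribosomal proteins and -0.04 for oxidative phosphorylation. Without the 4 arrays of another floor the HCC differences turned for B cells and lymph node (-0.04) and lung epithelium (-0.19). Red blood cells were then -0.90 and interferon response -0.42, and these remaining lists still did not pass under camera. In the colon pairs the tumor endothelium score was higher in 7 of 7 pairs, by 0.16 (exact sign-flip p = 0.0156, the smallest that 7 pairs can give, adjusted 0.271).

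The angiosarcoma, a tumor of vessel-lining cells, had a pan-endothelial level of 5.02 in its primary and 4.75 in its lymph node metastasis, both below the means of HCC primaries without metastasis (5.77) and of CC primaries (5.35). On these 2 arrays PECAM1 was 10.72 and 11.49, CDH5 was 4.61 in the primary and at the floor in the metastasis, the biliary list was 8.37 and 7.93, and KRT19, a keratin of bile duct epithelium, was 10.21 and 8.63. Among pan-endothelial genes, PECAM1 was at the floor on 0 of 61 arrays, VWF on 17 and CLEC14A on 30.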
